A study of Homo sapiens with 48 samples.

How the data were processed

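CUT&RUN releases DNA next to an antibody-bound protein with a nuclease tethered to that antibody, and the released fragments are sequenced. Per the labels' protocols, HT1376 bladder cancer cells were lightly fixed before antibodies against ARID1A, SMARCA4, H3K27ac, H3K4me3 or H3K27me3, or a nonspecific IgG, were added. The series lists 48 samples, of which 42 had a peak list that was used here. The 6 IgG samples were not analysed here.

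Per the submitters' processing notes, Bowtie2, Picard and MACS2 were used with the hg38 build, and their versions and settings are not given in the sources used here. The deposited files are peak lists, with each library called on its own. There were 36 narrow lists, for ARID1A, SMARCA4, H3K27ac and H3K4me3, and 6 broad lists, for H3K27me3. In each deposited list the authors' caller gave a score per peak, a fold (ratio of the pileup to the local background), and the −log10 of the p-value and of the q-value. The lowest −log10 p was 5.00 over the narrow lists and 1.00 over the broad lists, so the broad lists hold many domains of weak evidence. These folds and scores are the authors' own values and were used only to rank, filter or describe peaks within a list.

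Groups and repeat numbers were taken from the labels, and nothing in the labels says whether repeats were separate cultures. The p-values for peak number and for likeness of libraries with the same label therefore measure the spread between these libraries, which may be technical. The p-values of Fisher's exact tests, random gene lists and sign tests run over genes, sites or chromosomes. They take the libraries as fixed and hold no spread between them. For SMARCA4 and the histone marks, some libraries shared every label, repeat number included. They are called library 1 and library 2 here, a numbering that carries no order and pairs nothing.

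Peaks on chromosomes 1 to 22 and X were kept. A pair of regions overlapped when they shared at least 1 base. The ARID1A peaks of all 12 libraries were merged into 21205 regions, and each region was scored as present or absent in each library. Peak numbers were compared on the log2 scale with two-sided exact permutation tests. The comparison of CPI-0209 with DMSO permuted labels within each of the 3 combinations of line and dox. Overlap of ARID1A sites with other targets was set beside 1000 random placements of the same sites on the same chromosome. Each chromosome ran from the lowest to the highest coordinate in any list, since no genome sequence was used here, so assembly gaps were not excluded.

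Gene names and coordinates came from the RefSeq table of GRCh38.p14, the same primary assembly as hg38, with 19974 protein-coding genes on the chromosomes kept. That table has no strand and no exons. The design called for windows at transcription start sites; windows around both annotated ends of each gene were used instead, 1 kb to each side for peaks and 2 kb for H3K27me3. Exons of ARID1A could not be checked, so peaks inside the whole gene interval were counted. For H3K27me3 the better covered of the 2 ends was taken. The 13 gene lists, with 355 different genes that all matched the table, were fixed before the data were examined and tested with Fisher's exact test and Benjamini-Hochberg adjustment. The comparisons and most alternatives were also fixed then. After the data were examined, sites within 10 kb of a gene were counted and compared with 10000 random lists matched on gene length in 20 bins. Induced ARID1A sites of either treatment alone were also defined after the data were examined. The class of sites in at least 2 of 4 induced libraries was added to the 10 kb test last, which raised the number of tests to 52 and lowered the adjusted p of the DMSO-only lists. The H3K27me3 threshold of a −log10 q of at least 1 and the recovery of depth also came after the data were examined.

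The rule for named genes was fixed in advance. It took ARID1A, SMARCA4 and EZH2. It took the 20 genes with an ARID1A peak at a gene end in all 4 induced libraries and none of the other 8, ranked by mean percentile of fold within each library, and the 5 sites over 10 kb from any gene end by the same ranking. It took up to 6 members of each list. For SMARCA4, H3K27ac and H3K4me3 it took 10 genes with a peak in every library of a label group and none of the group compared, and for H3K27me3 the 10 genes with the largest difference in window coverage. Whether a library of the other group had a peak over the same position, outside the window, was checked after the data were examined. Other genes, and list members beyond these, were named after their values were seen.

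Read totals are not in the files. The scale factor and background pileup of each narrow list were recovered from the authors' fold and −log10 p, because the caller's p is a Poisson tail of the same pileup and background. The pair was accepted when it gave the −log10 p to within 0.001, and the share of tested peaks so recovered was 100% in each narrow list. The lowest background level that recurred, divided by the scale factor, served as a relative depth. On simulated data with 3 known settings this level was recovered with a largest error of 3.06e-11%. Those data came from the same Poisson formula, so this checks the recovery and not whether the level follows read depth. The call of regions present in 4 libraries and absent from 8 was tested on 20000 simulated sites with 1500 planted. It recovered 86.3% of these, where the simulated detection rates allow 85.0%, with 0 false calls. Random calls were simulated independently in each library, which makes false calls all but impossible, and background regions shared between libraries were not simulated. The permutation test of 4 against 4 gave p under 0.05 in 2.80% of 1000 simulations with no effect. The list test found the 1 enriched list planted among 13, with 0 false calls.

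The alternatives were a −log10 q of at least 5, total bases covered, peaks merged within 1 kb, all sequences, the repeat number as a block, each library left out, a 2.5 kb window, other overlap rules and other backgrounds. Analyses used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.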

Results

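Binding of the chromatin remodeller subunits ARID1A and SMARCA4 and the histone marks H3K27ac, H3K4me3 and H3K27me3 were profiled by CUT&RUN in HT1376, a human bladder cancer line described by the submitters as ARID1A mutant. ARID1A is the DNA-binding subunit of canonical BAF complexes and SMARCA4 is their ATPase. A clonal HT1376 line with a doxycycline-inducible ARID1A gene, here the ARID1A line, was set against a control line with the inducible system alone. Cells with dox received 50 ng/ml for 24 h, and all were then kept for 4 days in DMSO or in 250 nM CPI-0209, an inhibitor of EZH2, the enzyme that writes H3K27me3. ARID1A was profiled in 6 groups of 2 libraries. SMARCA4 was profiled in 12 libraries under 4 labels, with 4, 2, 2 and 4 libraries each, and every histone mark in 6 libraries under the same 4 labels, with 2, 1, 1 and 2 each. Of the 6 ARID1A groups, no SMARCA4 or histone library is labelled ARID1A line, CPI-0209, dox or control line, DMSO, dox, while ARID1A line, DMSO, dox and control line, CPI-0209, dox each have 2 times the libraries of the other labels. Comparisons of SMARCA4 and histone marks hold only if these labels are right. Read depth is not given in the files, and the relative background level of the narrow lists ran from 0.146 to 1.02.

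The first question was whether induced ARID1A occupied chromatin. ARID1A peaks appeared in number only when the ARID1A line had received dox, which is called the induced state here. The 4 induced libraries held 8909 ± 2402 peaks (SD, n = 4; range 6119 to 11501). The same line without dox held 251 ± 84.9 (SD, n = 4) and the control line with dox 229 ± 79.3 (SD, n = 4). Dox raised the peak number in the ARID1A line 36.3-fold, a log2 difference of 5.18 ± 0.35 (SE), and the ARID1A line exceeded the control line under dox 40.0-fold, a log2 difference of 5.32 ± 0.36 (SE). Both differences had p = 0.0286 in the exact two-sided permutation test (n = 4 and 4), the smallest this design allows. Without dox, the ARID1A line did not differ detectably from the control line with dox (log2 difference 0.14 ± 0.41 SE, exact permutation p = 0.60, n = 4 and 4). Permuting within treatment gave p = 0.0556 for both, the smallest this exact permutation allows, with the same log2 differences.

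**Figure D1:**
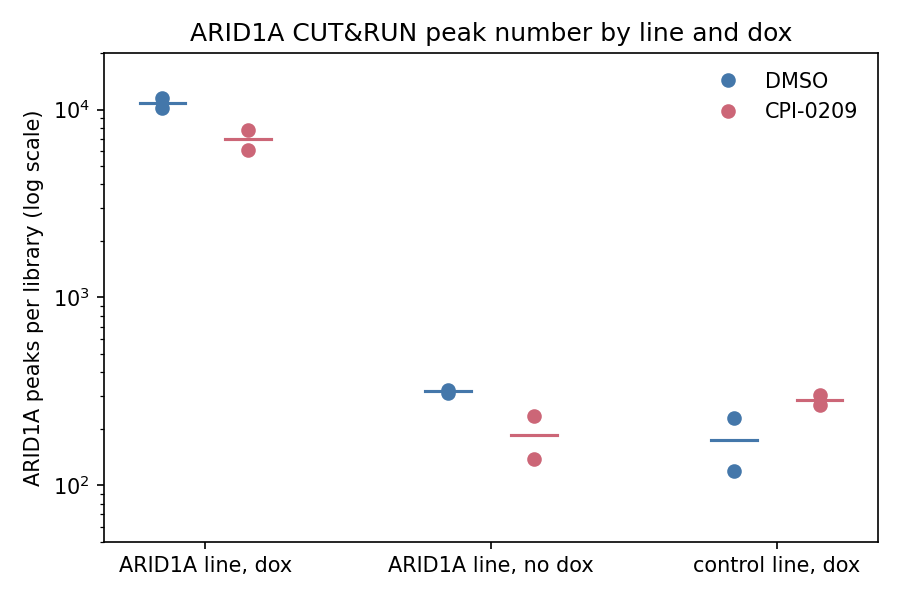
ARID1A peaks per library on a log axis, by line and dox, with DMSO in blue and CPI-0209 in red; each point is a library and each bar the mean of 2. The 4 induced libraries lie between 6119 and 11501 peaks and the other 8 between 119 and 323.

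Of the 21205 merged ARID1A regions, 1807 were present in all 4 induced libraries, and 1666 of these were in none of the other 8 (924 with a −log10 q of at least 5, and 2552 without the induced CPI-0209 repeat 1 library). Among those 1666 sites, 33.8% lay within 1 kb of a gene end, 66.2% overlapped a gene body, and 810 (48.6%) were more than 10 kb from any gene end. A peak at a gene end in all 4 induced libraries and no other was found for 617 genes. The highest ranked was C1QTNF2, a secreted C1q-related protein, with a fold over background of 9.13 ± 1.65 (SD, n = 4) and a peak at chromosome 5, 160370390 to 160370659 (hg38, DMSO repeat 2), at the upper end of the gene. HTRA3, a secreted serine protease, followed with 8.71 ± 2.21 (SD, n = 4; chromosome 4, 8269794 to 8270207). SEMA4F, a semaphorin, had 8.84 ± 3.20, and TEF, a PAR-domain transcription factor, 8.19 ± 1.34 (SD, n = 4 each). SETD2, the H3K36 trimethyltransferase, had 7.83 ± 2.32 (SD, n = 4), with a peak over its upper end at chromosome 3, 47163812 to 47164711.

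The other 15 genes of the ranking had mean folds between 6.46 and 7.97. They included BBS2 (7.78 ± 2.52), a BBSome subunit, the extracellular matrix genes LOXL1 (6.78 ± 1.35), TGM2 (6.97 ± 2.20) and TIMP4 (7.27 ± 3.36), and the Wnt ligand gene WNT7B (6.61 ± 1.21; all SD, n = 4). RABIF, POLI, QTMAN, VPS37C, SAYSD1, MAP4, SUN2, PUS7 and NT5C2 were also among them. The highest ranked distal site was at chromosome 18, 22223473 to 22224375, with a fold of 10.7 ± 2.34 (SD, n = 4). It was intergenic, and its nearest gene was that of the endoderm transcription factor GATA6, 20944 bases away. The next sites lay 43123 bases from ZFP36L2 on chromosome 2 (10.5 ± 4.82) and 44884 bases from SDC3 on chromosome 1 (8.22 ± 1.69), and sites inside FSTL4 (10.1 ± 3.25) and IQSEC1 (7.69 ± 1.44) followed (SD, n = 4). ARID1A, SMARCA4 and EZH2 themselves had no ARID1A peak at a gene end in any of 12 libraries, and 1 library had a peak inside the ARID1A gene (chromosome 1, 26696015 to 26782104). All 3 had an H3K4me3 peak at a gene end in 6 of 6 libraries.

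ARID1A sites at gene ends did not favour any of the 13 gene lists when presence in all 4 induced libraries was required. Between 0 and 1 members per list had such a site, against 3.62% of all genes, and every adjusted p was 1 (Fisher's exact test with Benjamini-Hochberg adjustment). At p under 0.05 unadjusted there were also 0 lists. The members with a site were ELF3, an epithelial ETS factor of the luminal list, CDH3 (P-cadherin) of the basal list, PHLPP1 of the cell cycle and PI3K list, HLA-C, PDGFRB and CSF1R. When presence in at least 2 of the 4 induced libraries was enough, 15.5% of genes had a site and 2 lists passed, with members named after their values were seen. Of the 22 basal and squamous genes, 9 had a site (among them CD44, CDH3, DSC3, ITGA6, ITGB4, SFN and TFAP2C; odds ratio 3.77, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0244). Of the 39 HOX genes, the homeobox genes of body patterning, 0 had a site (same exact test, Benjamini-Hochberg adjusted p = 0.0244). The test counts neighbouring HOX genes as independent, so this p may be too small. The other lists did not pass, including BAF subunits (7 of 23, with SMARCB1 and SMARCA2) and Polycomb-regulated developmental factors (3 of 60, BARX1, DLX2 and SIX2; exact test, Benjamini-Hochberg adjusted p = 0.0847). Luminal urothelial genes had 2 of 24, AP-1 and TEAD genes 3 of 21, PRC2 and PRC1 subunits 2 of 22 and ribosomal and housekeeping genes 3 of 36. Interferon and antigen presentation genes had 2 of 30, cell cycle and PI3K regulators 5 of 18, and the fibroblast, leukocyte and neuronal markers 1, 1 and 4 of 20 each.

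Counting sites within 10 kb of a gene, a measure chosen after the data were examined, brought luminal genes in as well, with members named after their values were seen. For sites in all 4 induced libraries 0 of 13 lists passed: luminal genes had 3 against 1.80 expected and basal genes 3 against 1.69 (permutation of lists, Benjamini-Hochberg adjusted p = 0.860 and 0.808), and HOX genes 0 against 1.74. Of 24 luminal urothelial genes, 15 had a site seen in at least 2 of 4 induced libraries, where random lists of matched gene length gave 7.32 (permutation of lists, Benjamini-Hochberg adjusted p = 0.0395 over 52 tests). They included PPARG, the nuclear receptor of luminal differentiation, GRHL2 and GRHL3, the ETS gene EHF, CDH1 (E-cadherin), UPK1B (a uroplakin) and the simple keratins KRT7, KRT8, KRT18 and KRT19. Of 22 basal and squamous genes, 14 had a site against 6.62 expected (permutation of lists, adjusted p = 0.0312), among them TP63, EGFR and KRT5. HOX genes had 0 of 39 against 7.82 expected (permutation of lists, adjusted p = 0.0312). Neighbouring genes, such as the keratin genes or the HOX genes, can share a site or lack one together. Members were therefore not independent, which the random lists do not allow for, and these p-values may be too small. Matching random lists on H3K4me3 as well left the adjusted p (permutation of lists) at 0.0312 for each of the 3 lists.

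Sites present in all 4 induced libraries overlapped active-promoter and SMARCA4 regions far more than random positions did, and H3K27me3 domains less. On average 35.9% ± 2.61 overlapped an H3K4me3 peak (SD over 6 libraries) against 1.01% for random placements. Overlap with SMARCA4 peaks was 20.6% ± 12.3 (SD over 12 libraries; range 8.30% to 50.0%) against 0.0773%. For H3K27ac it was 1.65% ± 2.50 against 0.122%, with lists of very unequal length. H3K27me3 domains covered 5.13% ± 3.18 of the sites against 32.2% (SD over 6 libraries). In each of the 6 H3K27me3 lists the share lay below the lowest of 1000 random placements.

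The next question was how EZH2 inhibition changed ARID1A binding. Over the 3 states of line and dox the peak number under CPI-0209 did not differ from DMSO in a stable direction (log2 difference -0.23, exact permutation p = 0.491, n = 6 and 6), and with a −log10 q of at least 5 the difference was 0.13. In the induced state CPI-0209 libraries held 6973 ± 1207 peaks and DMSO libraries 10845 ± 928 (SD, n = 2 each), a log2 difference of -0.65 ± 0.20 (SE). An exact permutation test of 2 against 2 cannot give a p below 0.333, and the DMSO libraries also had the higher background levels, 0.719 and 0.547 against 0.516 and 0.403.

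The positions differed more than the numbers. Peak positions of the induced libraries overlapped best within a treatment, with a base-pair Jaccard index of 0.409 for the DMSO pair and 0.307 for the CPI-0209 pair, against 0.165 to 0.194 across treatments. There were 3583 sites in both DMSO libraries and neither CPI-0209 library (DMSO-only sites), and 1245 in both CPI-0209 libraries and neither DMSO library (CPI-only sites). The other pairings of the same 4 libraries gave between 166 and 434. Splitting 4 libraries in pairs allows 3 arrangements, too few for a test at 0.05.

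DMSO-only sites gathered near genes of urothelial identity, which are named after their values were seen. Within 10 kb they reached 10 of 24 luminal genes, where length-matched random lists gave 3.12 (permutation of lists with Benjamini-Hochberg adjustment over 52 tests, adjusted p = 0.0312), and 9 of 22 basal and squamous genes, where random lists gave 3.00 (adjusted p = 0.0312). The luminal members were CDH1, EHF, GRHL2, KRT7, KRT8, KRT18, KRT19, OVOL1, PPARG and UPK1B. A site inside PPARG at chromosome 3, 12405741 to 12406083, had a fold of 5.41, and a site inside GRHL2 at chromosome 8, 101603650 to 101604143, had 7.54 (means of 2 libraries). The basal members included CD44, CDH3, EGFR, ITGA6, KRT5, SFN and TP63. Other lists did not pass: cell cycle and PI3K regulators had 7 of 18 against 2.38 expected (permutation of lists, adjusted p = 0.0745), with CDKN1A, BTG2 and PIK3R1, and AP-1 and TEAD genes 6 of 21 against 2.46 (adjusted p = 0.265), with TEAD1, YAP1 and WWTR1. CPI-only sites reached 2 luminal genes (ERBB3 and OVOL1) and 1 basal gene (KRT6A), against 0.976 and 0.994 expected. The share of sites near luminal or basal genes was 22 of 3583 for DMSO-only and 3 of 1245 for CPI-only sites, a difference that Fisher's exact test did not separate (p = 0.167).

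CPI-only sites lay in H3K27me3 domains several times as often as DMSO-only sites. In the H3K27me3 list of the library labelled ARID1A line, CPI-0209, no dox, 38.7% of CPI-only sites (95% exact binomial interval 36.0% to 41.5%) and 6.95% of DMSO-only sites (6.14% to 7.83%) overlapped a domain. Across the 6 lists the CPI-only share ran from 19.3% to 41.4% and the DMSO-only share from 1.48% to 9.91%. The CPI-only share was higher on 23 of 23 chromosomes in 5 lists and on 22 of 23 in the other (largest two-sided exact sign test p = 5.72e-06), and odds ratios ran from 3.77 to 16.5. Chromosomes of the same libraries are not replicates of the treatment. This p holds no spread between libraries and does not test CPI-0209 against DMSO. Per induced library, in that same H3K27me3 list, 21.5% and 21.2% of all ARID1A peaks lay in a domain under CPI-0209, and 7.47% and 8.11% under DMSO. Random placements of the CPI-only sites gave 18.0% in that list and 25.3% in the library labelled control line, CPI-0209, dox, library 2, where 41.4% was observed. In the other 4 lists the CPI-only share lay at or below the random mean, so it is raised over DMSO-only sites in 6 lists and over random positions in 2.

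Developmental regulators, also named after their values were seen, were among the genes near CPI-only sites. Of 60 Polycomb-regulated developmental factors, 5 had a CPI-only site within 10 kb (ALX4, BARX1, SIX2, SOX18 and WT1) against 2.12 expected, which did not pass (permutation of lists, adjusted p = 0.431). DMSO-only sites reached 1 of these genes, SOX18. The site by SIX2, at chromosome 2, 45009580 to 45010174, had a fold of 6.49 and lay in a domain in 5 of 6 H3K27me3 lists, as did a site inside WT1 at chromosome 11, 32400035 to 32400363, with 3.90. The sites by ALX4 and BARX1 did so in 3 lists each and the one by SOX18 in 1. At gene ends, named after their values were seen, the highest ranked of 273 genes bound under CPI-0209 alone was CXCL8, the chemokine interleukin-8, with a fold of 12.5 ± 1.22 (SD, n = 2). The cell cycle repressor E2F7 had 10.7 ± 2.65 (SD, n = 2). Of 915 genes bound under DMSO alone, ULBP3, an NKG2D ligand, ranked highest at 13.8 ± 1.09, and the ceramide synthase gene CERS5 had 12.6 ± 0.95 (SD, n = 2).

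**Figure D2:**
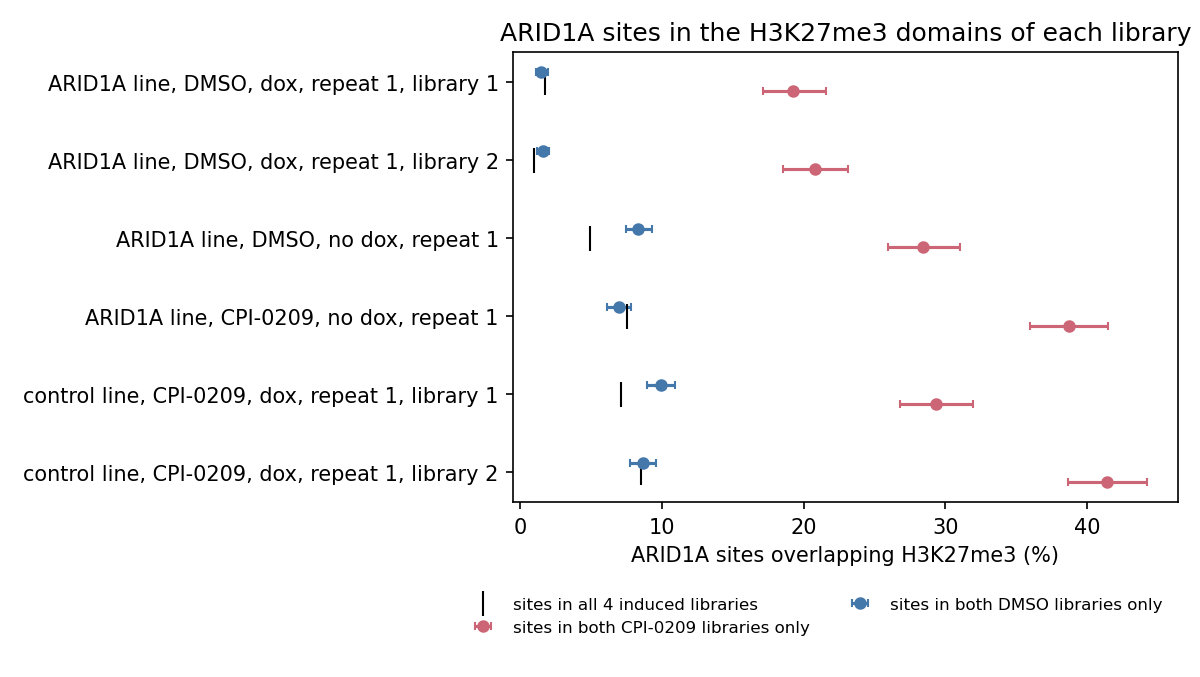
Percent of ARID1A sites that overlap an H3K27me3 domain in each of the 6 H3K27me3 libraries, for CPI-only sites (red), DMSO-only sites (blue) and sites in all 4 induced libraries (black ticks); bars are 95% exact binomial intervals. CPI-only sites lie between 19.3% and 41.4% and DMSO-only sites between 1.48% and 9.91%.

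SMARCA4 was profiled to follow the ATPase of the complex. The 3 label comparisons of SMARCA4 peak number had too few libraries to pass 0.05, so no difference is excluded. In the ARID1A line without dox, CPI-0209 and DMSO libraries did not overlap in peak number (1835 and 3069 against 858 and 1336). The libraries with dox ranged widely, from 553 to 4304 for ARID1A line, DMSO and from 1021 to 3763 for control line, CPI-0209. In the ARID1A line under DMSO there were 1962 ± 1626 peaks with dox (SD, n = 4) and 1097 ± 338 without (SD, n = 2), a log2 difference of 0.50 ± 0.69 SE (exact permutation p = 0.60; smallest possible 0.0667). Without dox, CPI-0209 libraries had 2452 ± 873 peaks, 2.22-fold the DMSO number (log2 difference 1.15 ± 0.49 SE, exact permutation p = 0.333, the smallest possible, n = 2 and 2). Under CPI-0209 the control line with dox had 1913 ± 1270 peaks (n = 4), a log2 difference from the ARID1A line without dox of -0.52 ± 0.56 SE (exact permutation p = 0.60; smallest possible 0.0667). Single libraries moved 2 of these differences by over 1.5 times. The dox difference was 0.0011 without library 2 of ARID1A line, DMSO, dox, repeat 2 and 0.99 without library 1 of that repeat, and the line difference was -0.15 without ARID1A line, CPI-0209, no dox, repeat 2 and -0.91 without library 2 of control line, CPI-0209, dox, repeat 1.

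Genes with SMARCA4 at an end in every library of a label group and none of the compared group were few where presence in 4 libraries was required. With dox against without there were 7, led by ME2, the mitochondrial malic enzyme (fold 5.37, n = 4), and NAP1L1, a histone chaperone (5.29), with BEND6, DST, SBSPON, MATN2 and ANKEF1. The opposite pattern held for 74 genes, led by ABRACL (7.02, n = 2), ANGPTL6, PPAN and the mismatch repair gene MLH3 (6.74). CPI-0209 against DMSO without dox gave 686 genes, among the top ranked PMF1 (8.49), ITPR3 (8.47), the squamous keratin KRT16 (8.38) and the proteasome subunit PSMD12 (9.02, n = 2), and 66 in the opposite direction. The CPI-0209 lists were the longer, 1835 and 3069 peaks against 1336 and 858 under DMSO. They also held more peaks within 1 kb of a gene end, 70.5% and 65.0% against 49.5% and 49.9%. The split of 686 and 66 may follow from this, and absence from a list is not absence of binding. KRT16 and ITPR3 were also among the 292 genes bound in the ARID1A line without dox and in no control-line library under CPI-0209. The opposite pattern held for 14 genes, with F2RL1 (5.17, n = 4) and the BAF subunit gene ACTL6A (3.44). FKBP9 and MBOAT1, named after their values were seen, alone had SMARCA4 at an end in all 12 libraries. Per library, between 0 and 6 members of each fixed list had SMARCA4 at an end.

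SMARCA4 libraries with identical labels differed in where they met ARID1A sites. Among those labelled ARID1A line, DMSO, dox, library 1 of repeat 1 covered 19.4% of CPI-only sites and 0.67% of DMSO-only sites, while library 2 covered 0.321% and 12.0%. In repeat 2, library 1 covered 5.86% and 0.307%, and library 2 covered 1.93% and 29.5%. Each of these 4 differences went one way on every chromosome where the classes differed (adjusted Fisher p at most 5.61e-32). In the other 8 SMARCA4 libraries the DMSO-only share (2.04% to 11.2%) was above the CPI-only share (at most 5.70%), though not in Fisher's exact test for the 2 labelled ARID1A line, DMSO, no dox (Benjamini-Hochberg adjusted p = 0.106 and 0.0693). Every SMARCA4 library was closest in base-pair Jaccard index to another with its own label (12 of 12, with a mean of 0.0943 within labels and 0.0580 between, one-sided exact permutation p = 0.00219). A label of 4 libraries that held 2 conditions could give the same result, so this does not settle whether that label is right.

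**Figure D3:**
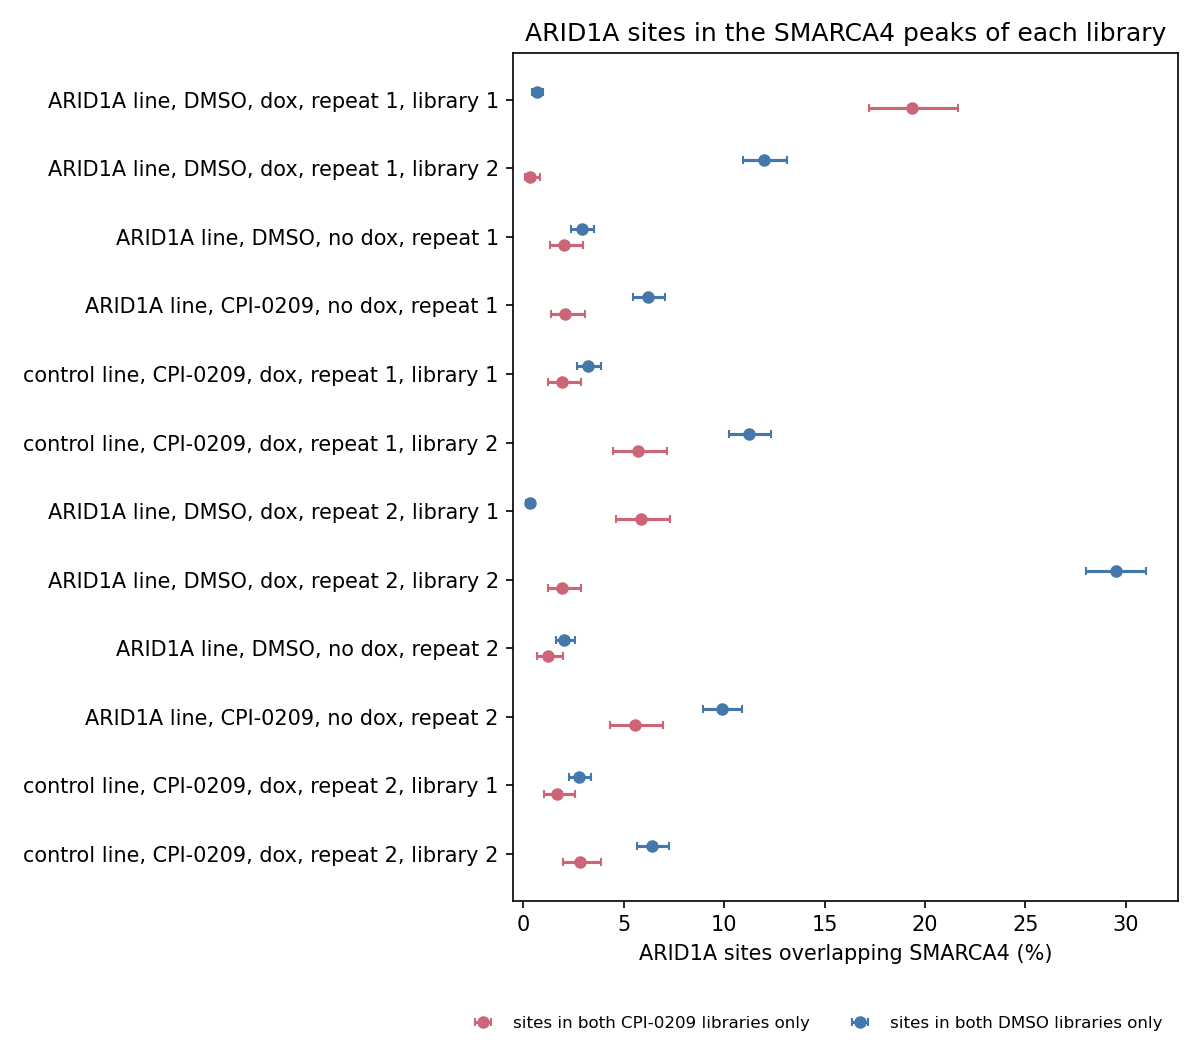
Percent of CPI-only (red) and DMSO-only (blue) ARID1A sites that overlap a SMARCA4 peak in each of 12 SMARCA4 libraries, with 95% exact binomial intervals. Of the 4 libraries labelled ARID1A line, DMSO, dox, both named library 1 are higher for CPI-only sites (19.4% and 5.86%) and both named library 2 for DMSO-only sites (12.0% and 29.5%).

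H3K27me3 marked the gene groups it is known for in every library. Windows at HOX genes were 92.2% ± 7.46 covered by domains and those of Polycomb-regulated developmental factors 89.3% ± 1.94 (SD over 6 libraries), against 27.2% ± 3.25 for all protein-coding genes. Neuronal markers reached 57.1% ± 5.01, fibroblast markers 47.9% ± 2.79 and leukocyte markers 35.6% ± 2.16, programmes of other cell types. Basal genes were at 20.5% ± 7.64, luminal genes at 17.5% ± 4.00, interferon genes at 14.1% ± 5.92 and PRC2 and PRC1 subunits at 12.9% ± 1.74. Cell cycle and PI3K regulators were at 9.69% ± 2.81, BAF subunits at 8.64% ± 4.25, AP-1 and TEAD genes at 7.56% ± 2.58, and ribosomal and housekeeping genes at 2.48% ± 2.11 (SD over 6 libraries).

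Coverage by called H3K27me3 domains did not follow the treatment labels in the same direction at every threshold. Coverage is not the amount of the mark, and depth was not recovered for these lists. A loss of the mark under CPI-0209 could therefore not be read from them. At the deposited threshold the library labelled ARID1A line, CPI-0209, no dox had 413 Mb in domains and the matching DMSO library 973 Mb. With a −log10 q of at least 2 the order turned, to 24.1 Mb and 0.0929 Mb, although CPI-0209 inhibits the enzyme that writes the mark. Libraries with identical labels also parted, with 0.0213 and 1.60 Mb at that threshold for ARID1A line, DMSO, dox and 0.243 and 8.21 Mb for control line, CPI-0209, dox. At a −log10 q of at least 1, libraries labelled CPI-0209 had 123, 56.9 and 6.78 Mb and those labelled DMSO 10.8, 6.37 and 1.66 Mb. A test of treatment was not run on these 6 libraries, and directions drawn from H3K27me3 labels are of the libraries so labelled. A wrong label on some of them was not tested and is not excluded.

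By window coverage at the deposited threshold, VGF, a neuropeptide precursor, VPS37A and GSE1 were the genes most covered in the library labelled CPI-0209 over the DMSO library without dox. In the opposite direction 165 genes were tied at full difference, the first by name including ACOD1, ATF7IP2 and BCOR. Each side was 1 library, and the DMSO list covered 973 Mb against 413 Mb. Of all genes, 9384 were higher in the DMSO library and 3191 in the other, so these genes may reflect list length. Between dox and no dox under DMSO, ANKRD24 (83.6 points), SCRT1 and the transcription factor gene MEF2C (80.1 points) were higher with dox, and HNRNPCL1, MYH13 and PSG11 were among 6 fully covered only without. Here the list without dox was the longer, 973 Mb against 644 and 525 Mb, with 7042 genes higher in it and 2165 lower. Under CPI-0209, ANKRD33B (98.8 points) and ZNF474 were higher in the control line with dox, and NCMAP (89.5 points) and RIPK3, a necroptosis kinase, in the ARID1A line without dox. The control-line lists were the longer, 1020 and 608 Mb against 413 Mb, with 2838 genes higher in them and 1526 lower.

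H3K4me3 was the most even measurement, with between 12373 and 15735 peaks in the 6 libraries, and 10266 protein-coding genes (51.4%) had a peak at an end in all of them. These included 36 of 36 ribosomal and housekeeping genes, 22 of 23 BAF subunits and 19 of 22 PRC2 and PRC1 subunits, against 3 of 39 HOX genes and 0 of 20 leukocyte markers. Genes with an H3K4me3 peak within 1 kb of an end in one label group and not in the other are given next. Some calls come from a peak that reaches the window in one list only: KDM2B, FOLR2, CD79A, TCEAL4 and GMPS ranked first by fold, but a library of the other group had a peak over the same position, so no change is shown for them. Leaving such genes out, a step chosen after the data were examined, 28 of 32 genes remained with dox against without under DMSO, among them MCAM (fold 7.88, n = 2), and 450 of 483 in the opposite direction, among them MFAP2 (20.4, n = 1). CPI-0209 against DMSO without dox kept 115 of 134 genes, with HSD17B7 (23.4), and 800 of 826 in the opposite direction, with the methionine sulfoxide reductase gene MSRB3 (34.6; n = 1 each). Under CPI-0209, 284 of 299 remained for the control line, with CYRIA (20.7) and the DNA demethylase gene TET1 (15.4, n = 2), and 38 of 43 for the ARID1A line. The same check left out at most 0.765% of the genes of any ARID1A, SMARCA4 or H3K27ac comparison, and none of those named here. Differences between H3K4me3 labels were not tested. Libraries with the same H3K4me3 label were no more alike than the rest, with a mean base-pair Jaccard index of 0.729 within labels and 0.748 between. The H3K4me3 genes that remained therefore differ between lists and do not show an effect of dox, treatment or line.

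H3K27ac lists were short and uneven, from 50 to 8729 peaks, and 3.36% to 7.56% of their peaks lay within 1 kb of a gene end. For the H3K4me3 lists that share was 71.1% to 77.8%. Between 0.339% and 10.5% of H3K27ac peaks overlapped an H3K4me3 peak shared by all H3K4me3 libraries. The share at gene ends for random positions was not measured. In the DMSO library without dox, 3.36% of peaks lay at gene ends and 0.610% on those shared H3K4me3 peaks. Library 1 of control line, CPI-0209, dox had 3.56% and 0.339%. Random placements of the ARID1A sites in all 4 induced libraries met H3K4me3 peaks at 1.01% on average. By this measure these 2 lists showed no excess over random positions. Background calls are therefore not excluded for the genes named below, TM4SF1 and FAM83G from that DMSO library included. The library labelled ARID1A line, CPI-0209, no dox had 8729 peaks and the DMSO library 1311. The libraries labelled ARID1A line, DMSO, dox had 50 and 1376, and those labelled control line, CPI-0209, dox had 1181 and 2696. Genes with H3K27ac under CPI-0209 and not DMSO numbered 665, with PSG2 (fold 9.70), SDCBP2 and the autophagy receptor SQSTM1 (8.32) among the top ranked, and 33 showed the opposite, led by TM4SF1 (7.09). The desmosomal cadherin DSC3 (7.51) was among 604 genes with H3K27ac in that library and neither control-line library. FSTL1 (6.67) was the 1 gene with H3K27ac in both libraries with dox and not without, and FAM83G (8.29) led the 45 with the opposite pattern. Differences between H3K27ac labels were not tested, and the 2 pairs of libraries with identical labels show how far single lists can part.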

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

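The test of library depth reported in this part was chosen after the result was seen.

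The effect of CPI-0209 on ARID1A peak number went in opposite directions in the induced ARID1A line and in the control line with dox, which is why it is listed here. Peaks under CPI-0209 were fewer in the induced line (log2 difference -0.65 ± 0.20 SE) and more numerous in the control line (0.78 ± 0.48 SE, n = 2 and 2 in each line). The ARID1A line without dox showed a fall as well, -0.81 ± 0.38 SE (n = 2 and 2), so a fall was also seen without induction. The difference between the lines was -1.43, with an exact permutation p = 0.0556, the smallest that 36 arrangements can give, so the design could not have passed 0.05. The control-line libraries held between 119 and 302 peaks, where small numbers of calls move the log2 ratio. Under CPI-0209 the induced libraries had background levels of 0.516 and 0.403, and under DMSO 0.719 and 0.547, so a part of depth in the fall of peak number stays open. No biological explanation was tested.

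Depth as the whole cause of the induced ARID1A peaks was tested and is argued against. The library labelled control line, CPI-0209, dox, repeat 1 had a background level of 0.407 and 267 peaks, while the induced CPI-0209 repeat 2 library had 0.403 and 7826 peaks, 29.3 times as many. Of 100 splits of the 12 libraries in 4 and 8, 1, the real one, gave as many regions in all 4 and none of 8, with 1666 regions against 13 for the highest other. Each other split puts a library of at most 323 peaks among the 4, so this count restates the difference in peak number, whose p was 0.0286 in the exact permutation test and 0.0556 when permuted within treatment, and excludes nothing beyond it. Induced ARID1A protein may therefore account for these sites, a hypothesis that rests on 1 clone and on the 29.3-fold difference at equal background.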

How the results depend on the processing

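A −log10 q of at least 1 for H3K27me3, the 10 kb lists matched also on H3K4me3, the label check at that q, and genes counted only with no peak of the other group at the same position were chosen after the data were examined. Of alternatives with a test, 86 kept direction and side of the threshold, 6 lost the threshold and 3 reversed. Of values and counts without one, 51 stayed within the spread between libraries or 1.5 times the count, 9 moved and 7 reversed.

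The log2 differences of ARID1A peak number for dox (5.18) and for line (5.32) kept p = 0.0286 in the exact permutation test under a stricter q, bases covered, merged peaks and all sequences, between 5.16 and 9.42. With treatment as a stratum they stayed at 5.18 and 5.32 with p = 0.0556, with the replicate block (repeat number held) at 5.18 and 5.32 with p = 0.0556, and with repeat number and treatment both held, added after the data were examined, with p = 0.125, since fewer exact permutations allow no lower p. Nothing pairs the repeats beyond a shared number. Leaving out each library gave 4.92 to 5.35 and 5.03 to 5.49. The line without dox against the control line was 0.75 at a −log10 q of at least 5 and, with each library left out, ran from -0.15 to 0.40, reversed without the ARID1A line DMSO repeat 1 library without dox (-0.0082, or -0.01) and without the control DMSO repeat 1 library (-0.15). CPI-0209 against DMSO ran from -0.38 to -0.07 with each library left out and reversed to 0.13 at a −log10 q of at least 5. With each library left out, SMARCA4 differences ran from 0.0011 to 0.99 for dox, so that 1 library removed the difference, from 0.78 to 1.52 for CPI-0209 and from -0.91 to -0.15 for line.

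Sites in all 4 induced libraries and no other numbered 924 at a −log10 q of at least 5, where fewer peaks enter, 1148 with 50% reciprocal overlap, and 1667 to 2552 with each library left out. Without the induced CPI-0209 repeat 1 library, the one with fewest peaks, there were 2552. Of the 1666 sites, 27.3% overlapped H3K4me3 by at least 50% of their length, against 33.8% by 1 base, and 0% met an H3K27me3 domain of −log10 q of at least 5. The H3K27me3 lists held only 3 to 24 such domains each, so this 0% was all but fixed in advance. With the same 2 rules, SMARCA4 overlap fell from 18.8% to 10.8% and 11.8%, and H3K27ac overlap from 1.71% to 0.740% and 0.680%, within 1 SD between libraries. With a site in at least 2 of 4 libraries, 2 gene lists passed instead of 0.

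At a −log10 q of at least 5, the log2 difference of H3K27ac peaks was 5.04 for CPI-0209 against DMSO and -4.17 for control against ARID1A line. Dox against no dox gave no value, since 1 library had no such peak. H3K4me3 stayed at -0.11 for CPI-0209 against DMSO. H3K27me3 coverage changed most. Dox against no dox went from -0.74 to -0.59, 0.99 and -4.10 at a −log10 q of at least 1, 2 and 5. CPI-0209 against DMSO went from -1.24 to 4.28, 8.02 and 2.00 at 1, 2 and 5, and control against ARID1A line from 0.93 to -2.65, -4.09 and -2.75. The cause was not tested. The H3K27me3 lists hold few domains of strong evidence (15 to 1516 at a −log10 q of at least 2, and 3 to 24 at 5), which limits any comparison of amount.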

Other observations

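The tests of depth, of random positions and of a mislabelled sample in this part were chosen after the result was seen; the test on stronger sites was written before it, but the need for its interval to clear the bound was added after its ratio was seen.

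CPI-only ARID1A sites lay in H3K27me3 domains more often than DMSO-only sites in each of 6 H3K27me3 libraries. Shallower CPI-0209 libraries alone are argued against, since missing peaks cannot add the 1245 sites seen in both CPI-0209 libraries and neither deeper DMSO library, against 434 for the highest other pairing. Random positions are argued against for the library labelled ARID1A line, CPI-0209, no dox, where the share was 38.7% and the highest of 1000 placements 21.4%, but in 4 of 6 lists the share was at or below the random mean. Weak peaks cannot be told apart: among the stronger sites of each class the ratios ran from 2.15 to 10.4 over the 6 lists, and the smallest was above the value of 2 set beforehand, but its 95% interval, 1.81 to 2.55, reaches below it. EZH2 inhibition may open H3K27me3 regions to ARID1A, a hypothesis that the 2.15 leaves open and that 2 libraries per treatment cannot test at 0.05.

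SMARCA4 libraries that share every label differed in the ARID1A sites they covered. Among the 4 labelled ARID1A line, DMSO, dox, the log2 ratio of overlap with CPI-only over DMSO-only sites spanned 9.50, from 4.66 to -4.84. Depth is argued against, because the 2 site classes moved in opposite directions in 4 of 6 pairs of these libraries. A wrong treatment label on some of them could give this span of 9.50 and remains a candidate explanation, as does any unrecorded difference between the libraries. The labels were used as given throughout, no library was regrouped, and no biological explanation was tested.

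Libraries with the same histone label were not closer to each other than to the rest. The mean base-pair Jaccard index was 0.324 within labels and 0.359 between for H3K27me3, 0.729 and 0.748 for H3K4me3, and 0.00961 and 0.0166 for H3K27ac, with 6 libraries per mark. For ARID1A it was 0.142 and 0.0204 (one-sided exact permutation p = 0.0001, the smallest of 10395 arrangements), and 8 of 12 libraries were closest to one of their own label. Across the 12 ARID1A libraries, 46 regions were in at least 2 of the 8 libraries without induction and in none of the 4 induced.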
